A study of Arabidopsis thaliana with 12 samples.

How the data were processed

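RNA was sequenced from the root tips (about 1 cm) of Arabidopsis thaliana seedlings. Per the labels' protocols, seedlings grown for 8 days at 22 °C with 16 h of light and 8 h of dark were moved for 24 h to half-strength Murashige and Skoog medium (MS) with or without NaCl. The NaCl concentration is not given in the sources used here. The 12 samples form 4 groups of 3, wild type (WT) and a line called 6-6, each on MS and on NaCl. The labels do not say what 6-6 is, and the series title concerns the gene ITPK4. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values may measure only the spread between samples.

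The submitters' processing notes name HISAT2, HTSeq and edgeR, with genome build TAIR10 and no versions. The 4 deposited tables, each for 1 pair of groups, have instead the column layout of Cuffdiff's gene-level output per the file headers, and the role of each named tool is not given in the sources used here. Each table holds 1 value per group in FPKM (fragments scaled for transcript length and library size, the unit of that layout) made by the authors, with the samples of a group already combined. Each also holds the authors' test statistic (a signed score), and the p-value and q-value that the authors deposited for each gene. The smallest p-value listed by the authors is 5e-05. The q-values of each deposited table equalled a Benjamini-Hochberg adjustment of its p-values over the tested genes to within 5.29e-07.

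The same group has slightly different FPKM in the 2 tables that hold it in the authors' deposited files, with median ratios of 0.979 for WT MS, 1.01 for WT NaCl, 0.988 for 6-6 MS and 1.02 for 6-6 NaCl. The tables were therefore treated as scaled separately, and each comparison was made within its own table. Values per sample were not used here, so no error between samples can be given for any value, the depth of the libraries is unknown, and the number of samples behind each group value is taken from the labels.

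The tests fixed before the data were examined needed values per sample and could not be run. These were a count model per gene with other tools, other scalings, a replicate block and samples left out as alternatives, the test of the difference in salt response between lines, and camera and fry on sample values. In their place, a gene was called when the authors' q-value was below 0.05. Its log2 fold change was computed as the log2 ratio of the 2 group FPKM, where log2(FPKM + 1) had been fixed, because the authors' p-values belong to the ratio. "Rose", "fell", "higher" and "lower" are used of single genes only where they were called. A gene with a group at 0 has no finite ratio and is given no fold.

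The 33557 gene codes of each table were matched to the RefSeq annotation of TAIR10.1, in which 32810 (97.8%) had an entry. Positions are TAIR10 positions as the files give them, with 1 added to the start. Of 28626 genes alone in their locus, 31.1% then had the same start and end as in RefSeq, and 0.433% had the same start without the addition. The files give 1 locus to 4249 genes that share it with another gene, whose values are uncertain where reads could belong to either. For 7 genes the files hold a date in place of the symbol, and the RefSeq symbol was used.

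The 26 gene lists, of 397 different genes, were fixed before the data were examined. They cover ABA signalling and synthesis, osmotic stress and LEA proteins, proline, sodium and potassium transport, inositol phosphate metabolism, phosphate starvation, reactive oxygen, cell wall expansion and cellulose, auxin, ethylene, jasmonate, iron acquisition, nitrate and sulfate uptake, aquaporins, cell cycle, root meristem, root hair, root cap, Casparian strip and endodermis, suberin, xylem and secondary wall, and phloem. Checks of tissue and handling were green tissue, heat shock, wounding and touch, and the circadian clock. Each list was set against all other tested genes with limma's cameraPR 3.58.1 (R 4.3.3, two-sided, preset correlation between genes of 0.01), adjusted by Benjamini-Hochberg over the 26 lists of a comparison and called below 0.05. The value entered per gene was the normal deviate of the authors' p-value with the sign of the fold change. That value was chosen after the test had first been run on the authors' test statistic, which takes large values for some genes with a high p-value. The results with the statistic are given as an alternative. No estimated correlation between genes can be had without values per sample. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the members of a list only.

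Genes were named by a rule fixed before the data were examined. It takes ITPK4, the 10 called genes with the highest and the 10 with the lowest log2 fold change among those with a symbol and sufficient expression, and from each list up to 4 members with the smallest p-value. Members with equal p-values were ordered by the size of the authors' test statistic, which that rule had not named. Such ties were common, since 2055 genes in WT salt and 2232 in 6-6 salt had the smallest p-value listed. A mean of at least 5 FPKM over the 2 groups replaced a planned minimum in CPM. The planned condition that the samples of the 2 groups do not overlap could not be applied. Genes named outside the rule are said to be so. Fold changes were compared between tables across genes with Pearson's r and Spearman's rho. Genes are not independent replicates, so these carry no p-value. No group is shared by the 2 tables of either such comparison. The overlap of calls is set beside the number that independent lists would share.

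Alternatives were fold change and q-value thresholds, pseudocounts of 0.1 and 1, a minimum of 1 FPKM, the authors' statistic read as a normal deviate, the same statistic rescaled and centred on the median gene, nuclear genes alone, genes alone in their locus, and for lists a correlation of 0.05, ranks and the authors' statistic. Reading the statistic as a normal deviate is stricter by construction, since its median lay below the normal deviate of the authors' p-value. The calculations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. They were tested on simulated data made from the WT NaCl and WT MS table with 19770 genes. Of 100 genes changed by a log2 of 1, 90 were recovered, and of 100 changed by 2, 98. There were 8 unchanged genes among the calls (4.08%). The gene values were simulated with the same normal error that the test then used, while the reported calls came from the authors' q-values. These gene rates therefore check the calculation only and do not give the error of the reported calls. Of 120 shifted lists 88 (73.3%) were called, and of 400 unshifted lists 4. For the lists only the gene codes came from that table. The values were independent normal deviates, with 1 added for genes of the shifted lists. Real genes can move together, so these list rates may not hold for the data.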

Results

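Gene expression was measured by RNA sequencing in root tips of wild type (WT) and the line 6-6, each moved for 24 h to MS medium or to MS with NaCl, with 3 samples in each of the 4 groups. The authors' tables compare NaCl with MS within each line and 6-6 with WT on each medium. Between 19465 and 19798 of 33557 listed genes were tested per table. The depth of the libraries is unknown, and no error between samples can be given for the group values.

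ITPK4 (AT2G43980, chromosome 2, 18208253 to 18211644, TAIR10), the gene of the series title, was strongly lower in 6-6 than in WT on both media. In the authors' deposited table for MS it stood at 24.9 FPKM in WT and 2.95 FPKM in 6-6, with a q-value of 0.00396. In the authors' deposited table for NaCl it stood at 27.7 FPKM in WT and 2.75 FPKM in 6-6, with a q-value of 0.00186. The log2 fold changes were -3.08 and -3.33. ITPK4 was not called for salt in either line, with log2 fold changes of 0.11 in WT and -0.15 in 6-6.

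**Figure D1:**
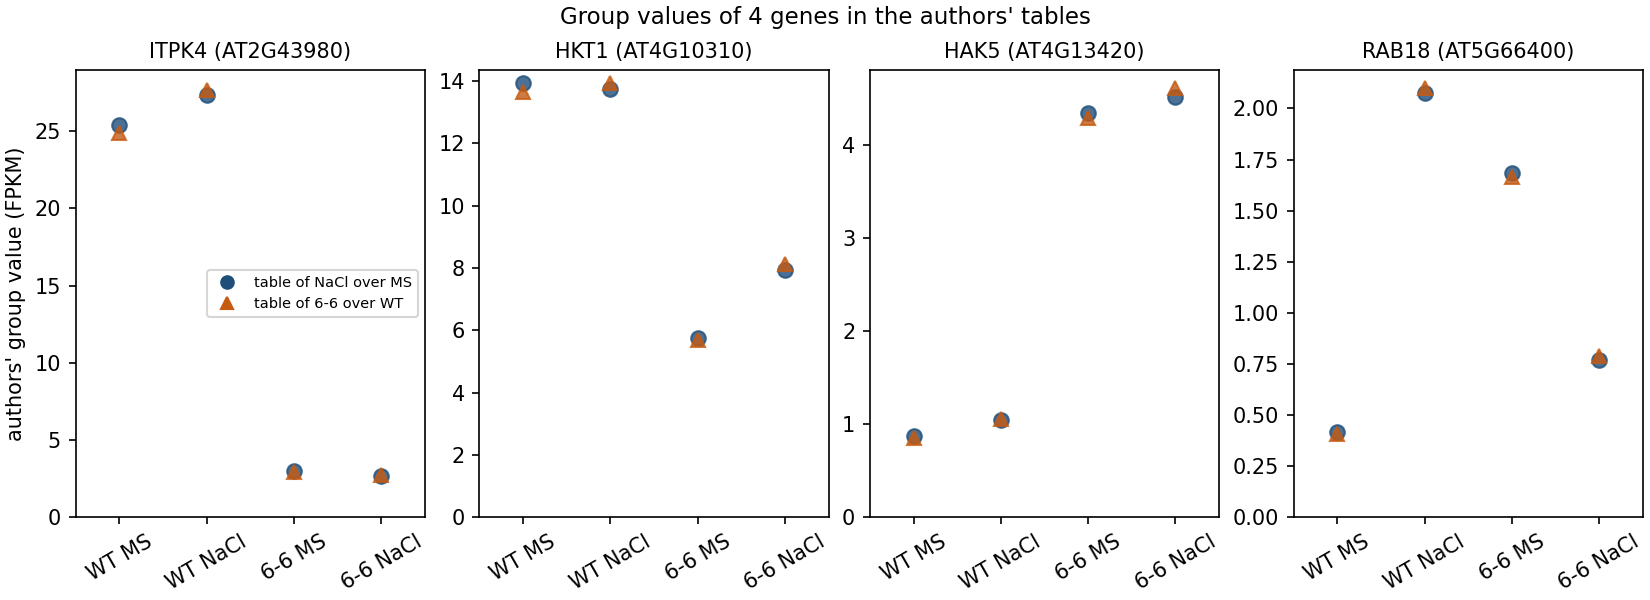
Group values in FPKM (linear axes from 0) of ITPK4, HKT1, HAK5 and RAB18 in the 4 groups, 1 point per group and table, with no error because the authors' tables hold 1 value per group. ITPK4 and HKT1 are lower and HAK5 higher in 6-6 on both media, while RAB18 is higher on NaCl in WT and lower on NaCl in 6-6.

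The comparison of WT NaCl with WT MS asks how WT root tips responded to salt. Salt changed a large share of the tested genes in WT. The lists of root hair and nuclear photosynthesis genes shifted up and those of aquaporins and cell cycle genes down under each set test run. The nitrate, LEA, cell wall, heat shock and touch lists also shifted up, but not under each. Each sample was a cut of about 1 cm, so the mix of cell types may itself have changed on NaCl in either line. Its part in these shifts was not tested. The heat shock and touch lists had been fixed as checks of handling. Whether handling differed between groups was not tested, here or in the other comparisons where either list was called. Of 19798 tested genes 4317 were called (21.8%), of which 2235 rose and 2082 fell, and 976 changed by a log2 of at least 1. The statistic read as a normal deviate gave 1671 calls, 935 up and 736 down.

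Among called genes with a symbol and a mean of at least 5 FPKM, the strongest rises in WT were those of the lipase gene TLL1 (log2 fold change 5.47), the transcription factor MYB67 (5.47), GSTU12 (4.96), the nitrate transporter genes NRT1.8 (4.96, a locus shared with another gene) and NRT2.1 (4.57), FACT (4.37), TH8 (4.31), ALD1 (3.78), GSTF6 (3.64) and ARPN (3.51). Under the same condition the lowest were UMAMIT17 (-3.75), GSTF12 (-3.52), the ABA receptor gene PYL6 (-3.00), GLIP2 (-3.00), OCT3 (-2.71), NSP3 (-2.37), OCT6 (-2.19), GulLO2 (-2.17), MSRB6 (-2.16) and HIR2 (-1.95).

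Of the 26 lists 9 were called in WT, 7 up and 2 down. With a correlation of 0.05 the calls of the nitrate, osmotic stress, cell wall, heat shock and wounding lists were lost, and with ranks those of the nitrate, osmotic stress and heat shock lists. Green tissue and photosynthesis genes rose in 13 of 18 and fell in 1, with a median log2 fold change of 0.69 and a cameraPR adjusted p of 1.22e-05, and LHCB1.3 rose by 1.87 and GAPA by 1.89. In every comparison, values of single LHCB and RBCS genes are uncertain where reads could belong to a near-identical copy. Root hair genes rose in 7 of 10 with none falling (median 0.39, adjusted p 0.000543), among them EXPA18 (0.70) and XTH14 (0.53). Cell wall genes rose in 10 of 20 and fell in 3 (median 0.28, adjusted p 0.00977), with XTH20 at 2.42, EXPA17 at 1.81 and XTH24 at -1.26. Nitrate and sulfate genes rose in 8 of 12 and fell in 2 (median 1.1, adjusted p 0.00977), including NRT3.1 (1.43), NIA2 (1.26) and SULTR1;2 (1.22). Osmotic stress and LEA genes rose in 8 of 16 and fell in 1 (median 0.31, adjusted p 0.0140), with KIN1 at 3.44, RAB18 at 2.32 and LEA4-5 at 1.44. Wounding and touch genes rose in 6 of 13 and fell in 1 (median 0.45, adjusted p 0.0174), with TCH3 at 2.98, and heat shock genes rose in 3 of 9 (median 0.75, adjusted p 0.0305), with HSP17.6C at 2.11.

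Aquaporin genes fell in 13 of 16 in WT and none rose (median -0.42, adjusted p 2.56e-06), with PIP2;4 at -1.13, PIP1;3 at -0.73 and TIP2;2 at -0.72. Cell cycle genes fell in 4 of 19 (median -0.23, adjusted p 0.00261), with CYCB1;2 at -0.36 and MCM5 at -0.33. These cell cycle calls were lost when the authors' test statistic was read as a normal deviate. Adjusted over the list alone, the counts of the called lists were the same except for heat shock (4 rose), wounding (7 rose), green tissue (2 fell) and cell wall (4 fell).

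The other 17 lists were not called in WT, and several held strong changes in both directions. ABA genes rose in 5 of 17 and fell in 6 (CYP707A3 2.1, HAI1 2.11, PYL6 -3.00). Sodium and potassium transport genes rose in 6 of 21 and fell in 3 (GORK 0.84, CHX17 -2.44, SLAH1 -2.66). Phosphate starvation genes rose in 7 of 16 and fell in 2 (RNS1 2.32, SPX1 -1.82, AT4 -1.65). Inositol phosphate genes rose in 6 of 22 and fell in 2 (MIOX1 2.26, MIPS1 -0.79). Suberin genes rose in 7 of 15 and fell in 3 (CYP86A1 1.74, MYB93 2.00). Reactive oxygen genes rose in 4 of 20 and fell in 8 (GSTF6 3.64, PER71 -1.69). Proline genes rose in 2 of 9 and fell in 1, with P5CS1 at 1.71 in a shared locus and PRODH1 at -0.71. Iron genes rose in 3 of 20 and fell in 5 (NAS4 1.78, CYP82C4 -1.37). Jasmonate genes rose in 1 of 12 and fell in 5 (LOX4 2.28, JAZ9 -1.16). Auxin genes rose in 3 of 25 and fell in 6 (IAA2 0.80, TAA1 0.54), and ethylene genes rose in 4 of 11 and fell in 4 (ETR2 -2.15, ACS6 0.67). Clock genes rose in 1 of 11 and fell in 3 (PRR9 -0.95). Casparian strip genes rose in 2 of 9 and fell in 3 (CASP5 -0.81), and xylem genes rose in 1 of 10 and fell in 1 (ACL5 -1.92). Root meristem genes rose in 1 of 7 and fell in 1, root cap genes fell in 1 of 4 and phloem genes fell in 1 of 4.

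**Figure D2:**
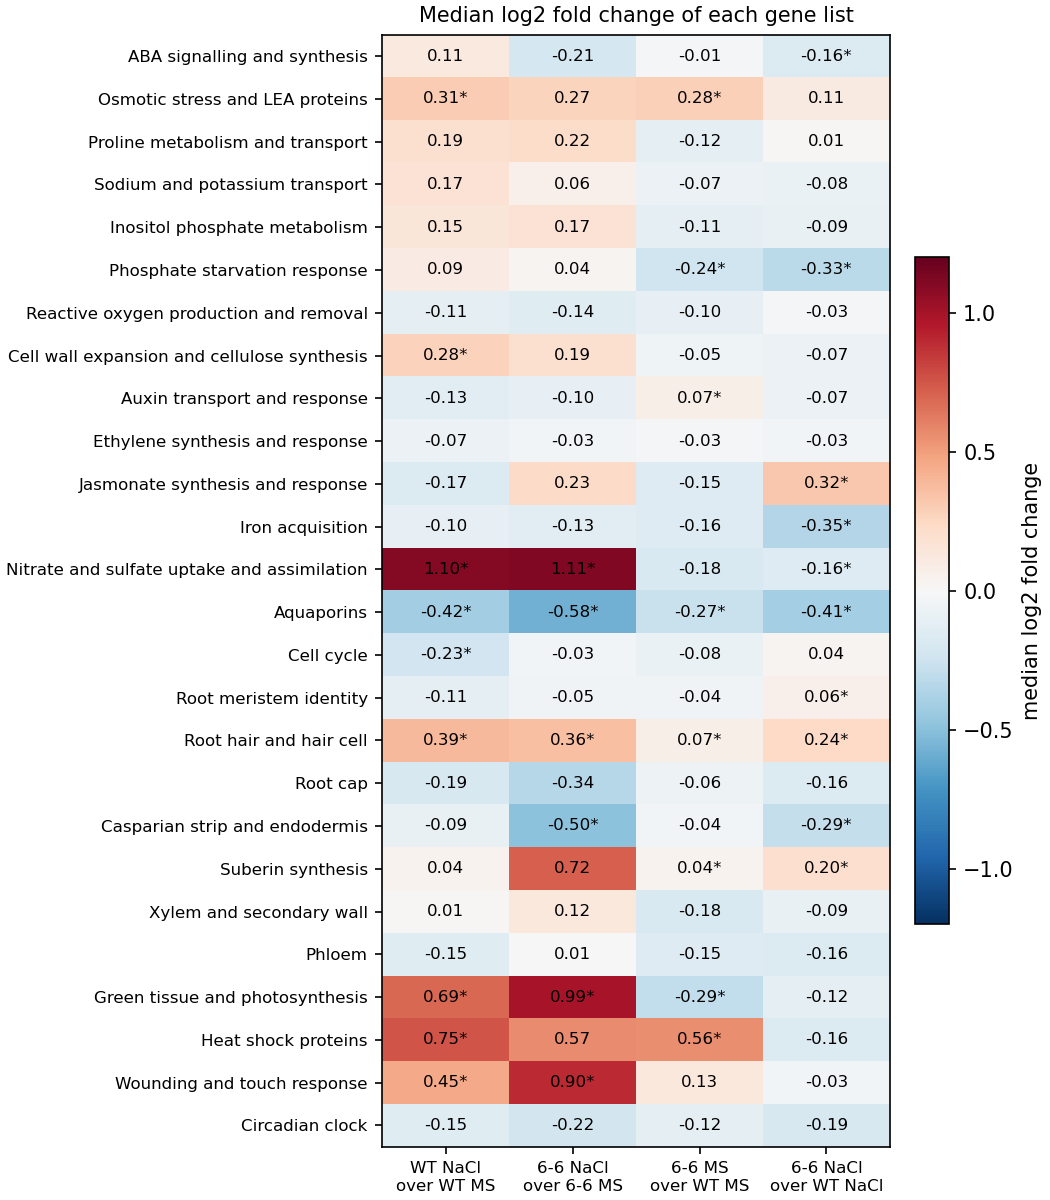
Median log2 fold change of each of the 26 gene lists in the 4 comparisons, with an asterisk where the cameraPR adjusted p was below 0.05. Aquaporins are the 1 list called down in all 4 comparisons, and root hair genes the 1 list called up in all 4.

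The comparison of 6-6 NaCl with 6-6 MS asks the same question in the line 6-6. Many genes moved as in WT, with TLL1, MYB67, GSTF6, FACT, TH8, NRT1.8 and NRT2.1 among the 10 highest called genes with a symbol and a mean of at least 5 FPKM in both lines. The photosynthesis and root hair lists again shifted up and the aquaporins down. The nitrate and touch lists shifted up and the Casparian strip list down, but not under each set test run. Of 19705 tested genes 4749 were called, of which 2706 rose and 2043 fell, and 1264 changed by a log2 of at least 1. With the statistic read as a normal deviate 1989 were called, 1182 up and 807 down. Of all 4749 called genes, 60 were organelle genes and each of them fell.

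Of called genes with a symbol and a mean of at least 5 FPKM, the highest in 6-6 were PRX52 (6.01), CYP702A6 (5.33), TLL1 (5.17), BCB (4.51), GSTF6 (4.37), MYB67 (4.35), FACT (4.31), TH8 (4.11), NRT1.8 (4.07, shared locus) and NRT2.1 (4.03). Under that condition the lowest nuclear genes were UMAMIT17 (-3.83), OCT3 (-3.73), GSTF12 (-3.03), GLIP2 (-2.82), PYL6 (-2.69), MSRB6 (-2.57), the auxin carrier gene PIN5 (-2.21) and NSP3 (-2.21), and the mitochondrial NAD2 (-2.08, shared locus) and ORF106F (-2.21, a call lost with the statistic read as a normal deviate) were also among the 10 lowest.

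In 6-6, 6 of the 26 lists were called, 4 up and 2 down. With a correlation of 0.05 the calls of the nitrate and wounding lists were lost, and with ranks those of the nitrate, wounding and Casparian strip lists. Photosynthesis genes rose in 12 of 16 and none fell (median 0.99, cameraPR adjusted p 1.96e-07), with LHCB2.1 at 2.98 and RBCS1A at 1.53. Root hair genes rose in 6 of 10 (median 0.36, adjusted p 0.0107), with XTH14 at 1.15 and EXPA18 at 0.93. Nitrate and sulfate genes rose in 8 of 12 and fell in 2 (median 1.11, adjusted p 0.0162), with SULTR1;1 at 1.81 and NIA1 at 1.29. Wounding and touch genes rose in 6 of 13 and fell in 1 (median 0.90, adjusted p 0.0306), with MYB15 at 3.79 and TCH3 at 2.11. Aquaporin genes fell in 13 of 16 and rose in 1 (median -0.58, adjusted p 2.18e-08), with PIP2;4 at -1.33 and TIP2;3 at -1.24. Casparian strip genes fell in 5 of 9 (median -0.50, adjusted p 0.0107), with CASP5 at -1.85. Adjusted over the list alone, 13 photosynthesis genes and 8 wounding genes rose and the other counts of these lists were the same.

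Among lists not called in 6-6, suberin genes rose in 8 of 15 and fell in 2 (FAR1 1.81, MYB93 1.72), cell wall genes rose in 9 of 20 and fell in 4 (XTH20 3.1, XTH22 1.91) and osmotic stress genes rose in 5 of 16 and fell in 3 (KIN1 3.05, RD29A 0.87, DREB2A -0.79). ABA genes rose in 3 of 16 and fell in 6 (CYP707A3 1.66), and iron genes rose in 3 of 20 and fell in 7 (BHLH39 -1.24, S8H -1.67). No cell cycle gene of 19 was called in 6-6. The meristem genes WOX5 (1.8) and PLT3 (0.67) rose, and JAZ10 (1.70) rose among the jasmonate genes.

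The salt responses of the lines were compared gene by gene. Across the 6024 genes called in either line, the log2 fold changes had a Pearson r of 0.87 and a Spearman rho of 0.85, and 92.3% had the same sign. There were 1574 genes that rose in both lines, where independent lists would share 302, and 1320 that fell in both, where they would share 214. Only 19 genes were called in opposite directions, 7 of them up in WT and down in 6-6 and 12 the reverse. RAB18 rose in WT (2.32) and fell in 6-6 (-1.13). In the authors' deposited tables RAB18 stayed low in every group, between 0.406 FPKM and 2.1 FPKM. Its rise in WT and its higher value in 6-6 on MS (2.04) share the WT MS group. Chosen after their values were seen, the sugar transporter gene SWEET11 moved from 0.53 in WT to -1.74 in 6-6, and AOC2, a jasmonate synthesis gene, from -1.27 to 1.03. The AOC2 calls and the SWEET11 call in WT were lost when the authors' statistic was read as a normal deviate. The difference in salt response between lines was itself not tested.

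**Figure D3:**
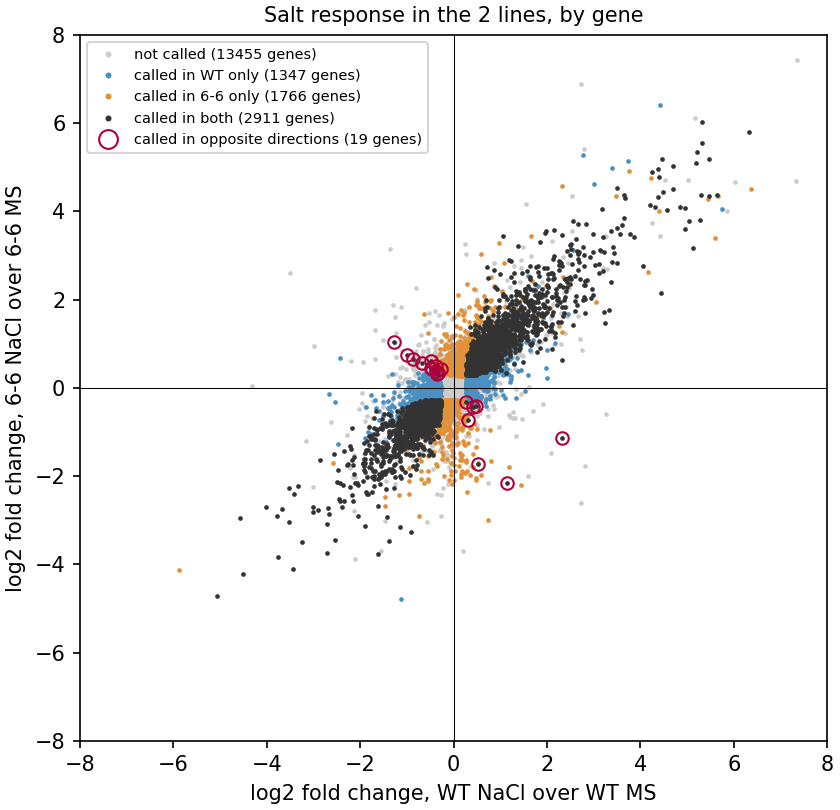
Log2 fold change of NaCl over MS in WT (horizontal) and in 6-6 (vertical), 1 point per gene tested in both, coloured by the line in which it was called, with the 19 genes called in opposite directions circled. Most called genes lie along the diagonal, and the genes called in 6-6 only that hang below 0 near the vertical axis include organelle genes.

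The comparison of 6-6 MS with WT MS asks how the lines differed without salt. Apart from ITPK4, the line 6-6 had less of the sodium transporter gene HKT1 and more of the potassium transporter gene HAK5. The LEA and heat shock lists shifted up relative to other genes, and the phosphate starvation, aquaporin and photosynthesis lists down, with few of their genes called. The LEA and heat shock shifts here and those on NaCl in WT share the WT MS group, so they are not separate observations. Neither list was called in the 2 comparisons without WT MS. Their medians were 0.27 and 0.57 for salt in 6-6, and 0.11 and -0.16 between lines on NaCl. Organelle transcripts were also higher in 6-6 on MS (median 1.33) and not on NaCl (median -0.25). The 1 18S rRNA gene that was checked was listed as holding too many fragments only in the 2 tables with 6-6 MS. Each of the other 2 tables also held 1 gene with that status, and the depth of the libraries is unknown.

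On MS 587 of 19465 tested genes were called, of which 220 were higher in 6-6 and 367 lower, and 128 differed by a log2 of at least 1, of which 102 were higher and 26 lower. The split depends on the threshold, the statistic and the scaling. A q-value below 0.01 left 126 higher and 144 lower, and the statistic read as a normal deviate gave 78 higher and 38 lower. The median tested gene lay at -0.07, and with the rescaled statistic the share of calls that were higher moved from 35.8% to 62.5% once values were centred on the median gene, against 37.5% here. Among the calls, 43 of the higher genes were organelle genes.

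Among called genes with a symbol and a mean of at least 5 FPKM, the lowest in 6-6 on MS after ITPK4 were MRD1 (-1.86, shared locus), the marneral synthase gene MRN1 (-1.67), BCAT4 (-1.3, shared locus), HKT1 (-1.26), GSTF11 (-1.21), CYP702A5 (-1.09), UMAMIT14 (-1.04), MSRB4 (-1.03) and CLE13 (-0.92). The calls of MRD1, MSRB4 and CLE13 were lost with the statistic read as a normal deviate. Of the 10 highest under the same condition, 9 were organelle transcripts such as NAD2 (2.22, shared locus) and ORF294 (1.98), and the nuclear gene was GRP3S (2.25).

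Of the lists, 8 were called on MS, 5 up and 3 down. The suberin call was lost with a correlation of 0.05, with ranks and with the authors' statistic, the auxin call with a correlation of 0.05 and the root hair call with ranks. Osmotic stress and LEA genes were higher in 5 of 14 and lower in none (median 0.28, cameraPR adjusted p 2.82e-10), with RAB18 at 2.04 and KIN1 at 1.38, and in 7 adjusted over the list alone. Heat shock genes had 1 higher of 7, HSP90.1 at 0.60 (median 0.56, adjusted p 0.00162). Auxin genes had 1 higher of 26, GH3.3 at 1.03 (median 0.07, adjusted p 0.00735), root hair genes 2 higher of 10, LRX1 at 0.55 and PRP3 at 0.50 (median 0.07, adjusted p 0.00735), and suberin genes 1 higher of 15, CYP86A1 at 0.68 (median 0.04, adjusted p 0.0423), with 1 also lower adjusted over the list alone. The calls of LRX1, PRP3 and CYP86A1 were lost with the statistic read as a normal deviate. Aquaporin genes had 1 lower of 16 over all genes and 5 adjusted over the list alone (median -0.27, adjusted p 0.000708). Phosphate starvation genes were lower in 3 of 16 and in 5 adjusted over the list alone (median -0.24, adjusted p 0.00138), with AT4 at -0.87. Photosynthesis genes were lower in 3 of 15 and in 5 adjusted over the list alone (median -0.29, adjusted p 0.00161), with LHCB1.3 at -0.75.

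Among lists not called on MS, 1 of 21 sodium and potassium transport genes was higher, HAK5 at 2.33, and 2 were lower, HKT1 and the shared-locus SKOR (-0.72, a call lost with the statistic read as a normal deviate). In the authors' deposited table HKT1 stood at 13.6 FPKM in WT and 5.69 FPKM in 6-6, and HAK5 at 0.853 FPKM and 4.29 FPKM. Inositol phosphate genes had 1 higher of 21, MIOX2 at 1.3, and 1 lower, ITPK4. Iron genes were lower in 3 of 20, with S8H at -1.31, and PER71 (0.87) was the 1 higher of 20 reactive oxygen genes. No ABA gene of 17, ethylene gene of 11, jasmonate gene of 10, proline gene of 8, meristem gene of 7, Casparian strip gene of 9, xylem gene of 9, phloem gene of 4, root cap gene of 4 or clock gene of 11 was called.

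**Figure D4:**
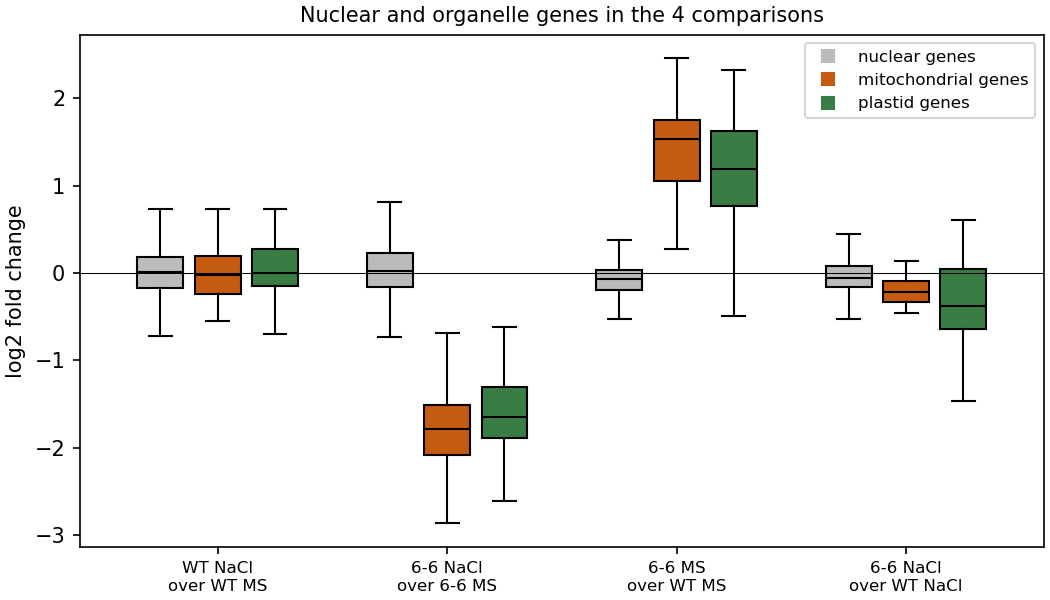
Log2 fold change of nuclear, mitochondrial and plastid genes tested in each comparison, as boxes from the lower to the upper quartile with the median, and whiskers to the farthest value within 1.5 times that range. Organelle genes lie above nuclear genes in 6-6 MS over WT MS and below them in 6-6 NaCl over 6-6 MS.

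The comparison of 6-6 NaCl with WT NaCl asks how the lines differed under salt. More genes were called than on MS. The jasmonate and suberin lists shifted up in 6-6 and the aquaporin, iron, phosphate starvation and Casparian strip lists down under each set test run. Root hair and meristem lists shifted up and nitrate and ABA lists down, but not under each. HKT1 stayed lower and HAK5 higher.

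Of 19772 tested genes 1327 were called on NaCl, with 601 higher in 6-6 and 726 lower, and 190 differed by a log2 of at least 1, of which 116 were higher and 74 lower. A q-value below 0.01 left 377 higher and 362 lower, and the statistic read as a normal deviate gave 139 higher and 67 lower. The median tested gene lay at -0.05, and the share of calls that were higher was 45.3% here, 44.6% with the rescaled statistic and 62.3% once that was centred on the median gene.

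Among called genes with a symbol and a mean of at least 5 FPKM, the highest in 6-6 on NaCl were E13L3 (3.45), the trypsin inhibitor gene TI1 (2.83), LTP2 (2.03), the peroxidase gene PA2 (1.8), BCB (1.52), EXT4 (1.47, with 87.5% of its 50-base words found once in the genome), MPL1 (1.37), LTP5 (1.34), AGD11 (1.29) and EXT12 (1.27). Under the same condition the lowest after ITPK4 were MRD1 (-1.72, shared locus), NRT1.8 (-1.34, shared locus), BHLH100 (-1.15), TIP2;3 (-1.13), WRKY30 (-1.11), CASP5 (-1.08), MRN1 (-1.07), NRT2.1 (-1.01) and CAB1 (-0.97), which the photosynthesis list calls LHCB1.3.

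On NaCl 10 lists were called, 4 up and 6 down. The calls of the ABA, nitrate, meristem and root hair lists were lost with ranks, and that of the ABA list also with a correlation of 0.05. Aquaporin genes were lower in 11 of 16 and higher in 1 (median -0.41, cameraPR adjusted p 1.08e-09), and in 14 adjusted over the list alone. Iron genes were lower in 9 of 20 with none higher (median -0.35, adjusted p 2.57e-05), with S8H at -1.35. Adjusted over the list alone, 12 were lower and 3 higher. Phosphate starvation genes were lower in 6 of 16 and higher in 1 (median -0.33, adjusted p 0.000279), with PS2 at -0.82 and RNS1 at 1.07. Casparian strip genes were lower in 2 of 9, among them CASP5, and in 7 adjusted over the list alone (median -0.29, adjusted p 0.000279). Nitrate and sulfate genes were lower in 3 of 12 (median -0.16, adjusted p 0.0116), and ABA genes lower in 4 of 17 and higher in 1 (median -0.16, adjusted p 0.0140), with HAI3 at -1.91. Suberin genes were higher in 4 of 15 (median 0.20, adjusted p 0.000218), among them FAR1 (0.75). Jasmonate genes were higher in 2 of 12, AOC2 (1.46) and JAZ10 (0.98), with a median of 0.32 and an adjusted p of 0.000279. Root hair genes were higher in 5 of 10 and lower in 1 (median 0.24, adjusted p 0.000730), among them PRP1 (0.57). Meristem genes were higher in 2 of 7, PLT3 (0.64) and WOX5 (1.00), with a median of 0.06 and an adjusted p of 0.0116. Adjusted over the list alone, suberin genes were higher in 7 and lower in 3, ABA genes lower in 8 and higher in 1, phosphate starvation genes lower in 10 and higher in 1, and jasmonate genes higher in 3. The calls of FAR1, AOC2, JAZ10, PRP1 and WOX5 were lost with the statistic read as a normal deviate.

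Among lists not called on NaCl, HAK5 (2.13) was the 1 higher of 21 sodium and potassium transport genes, and HKT1 (-0.78) and SKOR (-0.93) were lower. Osmotic stress genes were higher in 4 of 16 and lower in 4, with KIN1 at 0.99, KIN2 at 0.85, LEA14 at 0.79 and RAB18 at -1.42. MIOX2 was higher (0.94) among the inositol phosphate genes and PER71 (0.66) and DHAR1 (0.65) among the reactive oxygen genes. In the cell wall list XTH20 was higher (1.06) and XTH17 lower (-0.75), and ACS7 was lower (-1.01) in the ethylene list. LHCB1.3 (-0.97) was the 1 lower of 16 photosynthesis genes. No cell cycle gene of 19, proline gene of 9 or xylem gene of 10 was called.

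The differences between lines were compared between media. Across the 1634 genes called on either medium the log2 fold changes had a Pearson r of 0.47 and a Spearman rho of 0.41, and 74.5% had the same sign. There were 85 genes higher in 6-6 on both media, where independent lists would share 6.16, and 96 lower on both, where they would share 13.2, and 11 were called in opposite directions. Whether the difference between lines changed with the medium was not tested.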

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

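The fold change threshold was chosen before the data were examined, as were the pseudocount of 0.1 and the comparison over all tested genes, and the other alternatives were chosen after seeing the data, apart from the pseudocount of 1, which had been fixed as the scale to report and became an alternative. No paired analysis was possible because the authors' tables hold 1 value per group and no replicate numbers. For the same reason DESeq2, other scalings of counts, count filters, samples left out, fits of 6 libraries, fry, an estimated correlation and every alternative for the difference in salt response were not run. In the order WT salt, 6-6 salt, 6-6 against WT on MS and 6-6 against WT on NaCl, an absolute log2 fold change of at least 1 left 976, 1264, 128 and 190 genes, with a pseudocount of 0.1 it left 940, 1204, 122 and 171, and with a pseudocount of 1 it left 619, 818, 82 and 79, fewer by construction. The authors' statistic read as a normal deviate gave 1671, 1989, 116 and 206 calls, and its median ratio to the normal deviate of the authors' p-value was about 0.59 in each table. With it 23 of 108, 16 of 106, 21 of 46 and 41 of 80 named calls were lost and 0 were gained. A ratio below 1 lowers the number of calls by construction, and once rescaled the statistic gave 4736, 5240, 874 and 1692 calls. A call lost this way is therefore not shown to be weak. No pseudocount changed the sign of a named gene. A q-value below 0.01 gave 270 calls on MS and 739 on NaCl between lines. Between lines the larger side was lower among all calls and higher past a log2 of 1 or with the statistic read as a normal deviate (102 against 26 and 78 against 38 on MS, 116 against 74 and 139 against 67 on NaCl). The minimum of 1 FPKM, the rescaled statistic with or without centring, nuclear genes alone and genes alone in their locus kept each total of calls within 1.5 times. The split was not kept, since with centring the larger side between lines was higher, 431 against 259 on MS and 942 against 570 on NaCl. Called lists numbered 9, 6, 8 and 10. A correlation of 0.05 left 4 in WT salt, and ranks left 3 in 6-6 salt and 6 between lines on NaCl. Among single list results, that correlation ended 10 calls, ranks ended 12 and added 1, the authors' statistic ended 1 and added 4, and nuclear genes alone added 1. No list changed direction, and aquaporins stayed called in all 4 comparisons under each of these. The r between the lines' salt responses was 0.801 over all tested genes, 0.864 with a pseudocount of 0.1 and 0.888 over nuclear genes. The r between media was 0.277 over all tested genes, 0.456 and 0.453 with pseudocounts of 0.1 and 1, 0.477 with a minimum of 1 FPKM and 0.546 over nuclear genes, and the cause was not tested. Depth is unknown and its limit could not be assessed.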

Other observations

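In several groups of genes outside the fixed lists, members were called between the lines. Each group in this part was put together after its values were seen, so no test of a group as a whole is given. Aliphatic glucosinolate genes were lower in 6-6 on MS in 9 of 14, with BCAT4 at -1.3 (shared locus), CYP83A1 at -0.88, MAM1 at -0.86 and CYP79F2 at -0.85, and under salt 8 of 14 fell in WT (median -0.62), while in 6-6 4 fell and 1 rose (median -0.09), a difference that was not tested. The fall in WT and the lower values in 6-6 on MS share the WT MS group, so they are not separate observations. On NaCl 4 of the 14 were lower in 6-6. Of 6 indole glucosinolate genes, CYP79B3 (0.61), CYP79B2 (0.39) and CYP83B1 (0.37) were higher in 6-6 on NaCl and none was called on MS. Triterpene cluster genes were lower in 6-6 on MS in 7 of 8, among them MRN1 (-1.67), CYP705A1 (-0.81), CYP705A5 (-0.70) and CYP708A2 (-0.66), and 4 of the 8 were lower on NaCl. The calls of these 3 indole genes, and those of CYP705A1 and CYP708A2 on MS, were lost with the authors' statistic read as a normal deviate. Genes described as extensins included several higher in 6-6 on MS, with EXT4 at 1.45 and EXT10 at 1.3 (87.5% and 97.9% of their 50-base words found once in the genome), and with AT4G08410 at 1.53 and EXT6 at 1.32, whose values are uncertain because only 47.4% and 60.0% of their words are.

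The share of calls near ITPK4 was set against the rest of the nuclear genome, and a difference was not detected. Within 1 Mb of it 17 of 459 tested genes (3.70%) were called on MS against 2.78% elsewhere in the nuclear genome (Fisher's exact test, two-sided, p 0.249), and 27 of 460 (5.87%) on NaCl against 6.73% (p 0.510).

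All tests of explanations in this part were chosen after the result they measure was seen, except the test of shared reads among extensin genes. Organelle transcripts were higher in 6-6 MS than in WT MS, with a median log2 fold change of 1.33 over 91 genes and 43 called, and 60 of 90 fell from 6-6 MS to 6-6 NaCl. The tables argue against scaling, since nuclear genes lay at -0.071, against more green tissue, since the nuclear photosynthesis list lay at -0.29, and against a difference between the lines on both media, since organelle genes lay at -0.25 on NaCl. RNA without a poly(A) tail carried into the 6-6 MS libraries may be the source. The 1 18S rRNA gene checked was listed as holding too many fragments in both of the 2 tables with 6-6 MS and in 0 of the other 2. Each of those other 2 also held 1 gene with that status. The status rests on the number of fragments, so deeper 6-6 MS libraries could give it too, and depth is unknown. A difference between lines that the medium changes (1.33 on MS) cannot be told apart from such carried-over RNA, because the same 3 libraries make up the group.

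Of the nuclear photosynthesis genes on NaCl, 13 of 18 rose and 1 fell in WT, and 12 of 16 rose in 6-6 with none falling. Shoot tissue in the WT NaCl samples stays open, although the plastid genes had a median of 0.0044 in WT. Their summed FPKM was low, 122 in WT MS and 144 in WT NaCl. In 6-6 they had a median of -1.64 while the photosynthesis list lay at 0.99. That fall starts from the raised organelle values of 6-6 MS (summed plastid FPKM 273, against 105 in 6-6 NaCl), and mitochondrial genes fell as well (median -1.79). It therefore cannot show whether plastid genes track the photosynthesis list. Reads shared between near-identical copies are argued against as the whole source by the members outside the RBCS and LHCB families. These had a median of 0.64, with 7 of 7 called up in WT. Within the 2 families the question stays open. In WT LHCB1.3 rose by 1.87, while LHCB1.2 (-0.34) and LHCB1.1 (0.65) were not called. A response to salt, with a median of 0.99 in 6-6, stays a candidate explanation.

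On MS 14 of 32 tested genes described as extensins were higher in 6-6. The test of shared reads took all genes described with the word extensin, and it left the question open, since the 30 with mostly unique 50-base words had a median of 0.28 on MS and 12 (40.0%) were higher, against both of only 2 with mostly repeated words. The 30 include EXT6, with only 60.0% of its words unique. A longer differentiated part of the cut tip would raise the root hair and suberin lists, which were called up on NaCl (medians 0.24 and 0.20). The Casparian strip list at -0.29 was called the opposite way there, but it may stand for only a part of the differentiated tissue. The meristem list at 0.06 was also called the opposite way, with 2 of 7 genes called, and that list call was lost with ranks. These lists therefore do not decide the question on NaCl. On MS, where the Casparian strip list lay at -0.037 and no meristem or cell cycle list was called, a longer differentiated part cannot be told apart either. A difference between the lines on both media may explain part of the pattern, since the 14 genes higher on MS had a median of 0.45 on NaCl and 9 of them were called higher there.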
